A study of Homo sapiens with 12 samples.

How the data were processed

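Messenger RNA was measured by sequencing in 12 libraries of the Huh7 and Hep3B hepatocellular carcinoma lines, with 3 libraries for each of the hairpins shNC and shSLC6A8 in each line. Per the labels' protocols, RNA was taken with the RNAfast-2000 kit and libraries were built from 1.3 µg of total RNA with a SMARTer kit. The genome build was GRCh38.p14, per the submitters' processing notes; the aligner, the counter, the annotation and the strand setting are not given in the sources used here. Per the file headers, each line had a table of 62703 genes with an estimated count and a TPM value per library. The estimated counts were not normalized by the authors, as far as the deposited values show, since library sums differ and 13.5% to 15.6% of values per library have a decimal part of any size, taken over all listed genes with those at 0 included. The deposited TPM values are scaled for length and depth, per the file headers; they summed to 1000000 in Huh7 and to about 998326 in Hep3B, and they were not used for any test. The authors' tables also hold a fold change as a ratio, its log2 and a p-value with an adjusted p-value, per the file headers, from a comparison tool not given in the sources used here. Genes marked significant in the deposited tables all had an adjusted p-value under 0.05 and an absolute log2 fold change of at least 1. Other columns of sample values numbered 0.

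Groups were taken from the labels. Estimated counts were rounded to whole numbers. Genes of each line were filtered by edgeR's filterByExpr, scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05, the 6 libraries of a line alone and no covariate. SE was derived from the F statistic as the absolute log2 fold change over its square root and is approximate. The prior count of log2 CPM was 2. Common biological variation between replicates was 5.9% in Huh7 and 7.8% in Hep3B. The difference between lines was the interaction in one fit of 12 libraries. Shared calls were set against independent lists with Fisher's exact test, two-sided. Genes whose symbol another gene with more reads also has (1455) were kept under their identifiers, and gene symbols came from the deposited tables. Coordinates were matched by Entrez gene number to the RefSeq table of the same build for 257 of 269 named genes.

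Before the data were examined, 41 gene lists were fixed from general knowledge. They cover creatine and energy metabolism, hypoxia, stress, growth, liver cell identity, matrix, inflammation and markers of other cell types. Lists with at least 5 measured genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a line by Benjamini-Hochberg. Estimated correlations and fry were alternatives. Fry asks whether the genes of a list move and does not compare them with other genes. Named genes were chosen by a rule fixed at the same time. It took the measured members of the creatine list, the 8 largest changes per line and direction with all knockdown libraries on one side of all controls and a mean log2 CPM of 1 or more, and up to 2 members per list, line and direction by adjusted p. It also took the 6 largest shared changes per direction and the 4 clearest opposite changes. Both were taken among genes with a mean log2 CPM of 1 or more in each line. Genes of the list and shared parts could be left out for length, and some genes picked by the rule are not reported here.

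Alternatives were DESeq2 1.42.0 and its size factors, library totals, other filters and thresholds, limma-voom, a replicate block, 1 fit of all libraries, thinning to the smallest library and leaving out each library. Removal of gene length and GC trends (loess span 0.5), library totals for lists, the creatine list without SLC6A8, the list test of the difference between lines and alternatives for the correlation were added after the data were examined. In all, 18 settings per line for genes and 13 for lists gave 6634 recomputed values. The steps were tested on simulated counts with 200 changed genes. At a fold of 2, edgeR called 78.7% of changed genes in Huh7 and 83.9% in Hep3B, and at a fold of 1.5, 63.6% and 70.7%. Of unchanged genes, 16 of 16479 were called in Huh7 and 10 of 15709 in Hep3B. The simulation changed far fewer genes than the 10525 and 6488 called in the data, so these rates need not carry over. Depth ran from 21065965 to 28078068 estimated counts per library. Floors for a count of 0 used 3 counts over a group and cover counting error only. No pair of replicates agreed within sampling noise, and no library was left out.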

Results

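Messenger RNA was sequenced from Huh7 and Hep3B, a pair of established human hepatocellular carcinoma cell lines, after 24 hours of hypoxia. Each line carried either a control hairpin (shNC) or a hairpin against SLC6A8 (shSLC6A8), the transporter that brings creatine into the cell, and each of the 4 groups held 3 libraries. The series title places the question in how SLC6A8, raised by hypoxia, acts in liver cancer. All libraries analysed here are labelled as 24 hours of hypoxia, so the comparisons are between hairpins and none is with normoxia. Whether oxygen deprivation was equal in both hairpin groups cannot be told from these libraries. Library totals ran from 21065965 to 28078068 estimated counts, with 23156031 to 24565972 in Huh7 shNC, 23748949 to 28078068 in Huh7 shSLC6A8, 21065965 to 23237892 in Hep3B shNC and 24201940 to 27445278 in Hep3B shSLC6A8. Between 22209 and 25396 genes per library had at least 1 count. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Log2 fold changes are shSLC6A8 over shNC, ± SE, with n = 3 per group.

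SLC6A8 (ENSG00000130821, chromosome X, 153687926 to 153696593 in GRCh38.p14) was lower in every knockdown library of both lines. In Huh7 it fell from 36.4 ± 0.693 to 9.42 ± 1.39 TMM-scaled CPM (mean ± SD), a log2 change of -1.95 ± 0.09. In Hep3B it fell from 370 ± 8.24 to 34.5 ± 0.623 CPM, a log2 change of -3.42 ± 0.05. CPM were scaled within each line, so levels set across the lines are approximate; on that scale the knockdown libraries of Hep3B lay close to the Huh7 controls. The adjusted p-values of edgeR's quasi-likelihood test were 1.02e-11 in Huh7 and 2.13e-10 in Hep3B. In the authors' deposited table the log2 fold changes of SLC6A8 were -1.94 and -3.43.

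**Figure D1:**
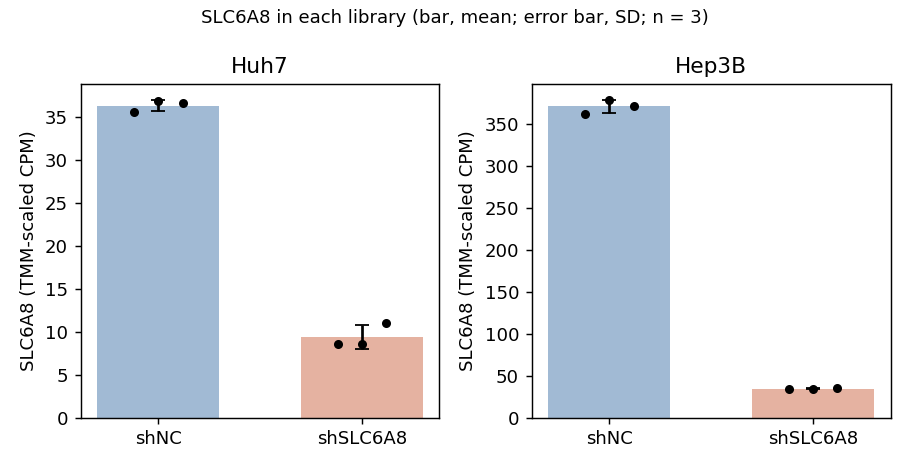
SLC6A8 in TMM-scaled CPM in each library of Huh7 (left) and Hep3B (right); bars are means, error bars are SD and points are the 3 libraries of a group. Means were 36.4 and 9.42 CPM in Huh7 and 370 and 34.5 CPM in Hep3B for shNC and shSLC6A8.

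In Huh7, hypoxia-induced, glycolytic, ATF4-driven and antioxidant genes were lower in the knockdown libraries, and genes of DNA replication and mitosis were higher. CA9, a carbonic anhydrase of hypoxic tumours (chromosome 9, 35673928 to 35681159), fell by 3.84 on the log2 scale (SE 0.26). TOP2A, the topoisomerase of dividing cells, rose from 154 to 458 CPM (log2 change 1.57 ± 0.06). G6PC1, the glucose-releasing phosphatase, rose by 3.16 (SE 0.18). Of 17022 genes tested, 10525 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 5253 higher and 5272 lower, and 2584 of them also changed by a log2 fold of 1 or more. The authors' deposited table marked 2585 genes at that fold limit; 2312 were called here in the same direction and 0 in the opposite one. With library totals the median log2 change of all genes in Huh7 was 0.105, against 0.001 with TMM, and 59.7% of calls were then higher, against 49.9%.

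Among the hypoxia-induced genes, targets of the hypoxia-inducible factors, 29 of 32 fell and 2 rose in Huh7 (30 and 2 adjusted over the list alone), with a median log2 change of -1.25. BNIP3, a mitophagy receptor, fell from 427 to 124 CPM. The members that rose were LOX, a collagen cross-linking enzyme (0.57 ± 0.06), and EPO, the erythropoietin gene (0.93 ± 0.15). Of 22 glycolysis genes 17 fell and 3 rose (17 and 3 adjusted over the list alone). The glucose transporter SLC2A1 fell by 1.92 and the kinase PGK1 fell by 1.43, while the liver isoforms PFKL and PKLR rose by 0.66 and 3.32. LDHB, a lactate dehydrogenase subunit, fell from 20.6 to 0.708 CPM. Camera gave adjusted p-values of 5.59e-36 for the hypoxia list and 2.88e-17 for glycolysis, and both calls held with an estimated correlation (p = 0.00507 and p = 0.0471). In all, camera called 24 of 40 lists in Huh7, at adjusted p-values of at most 0.0256, and 9 of them held with an estimated correlation.

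**Figure D2:**
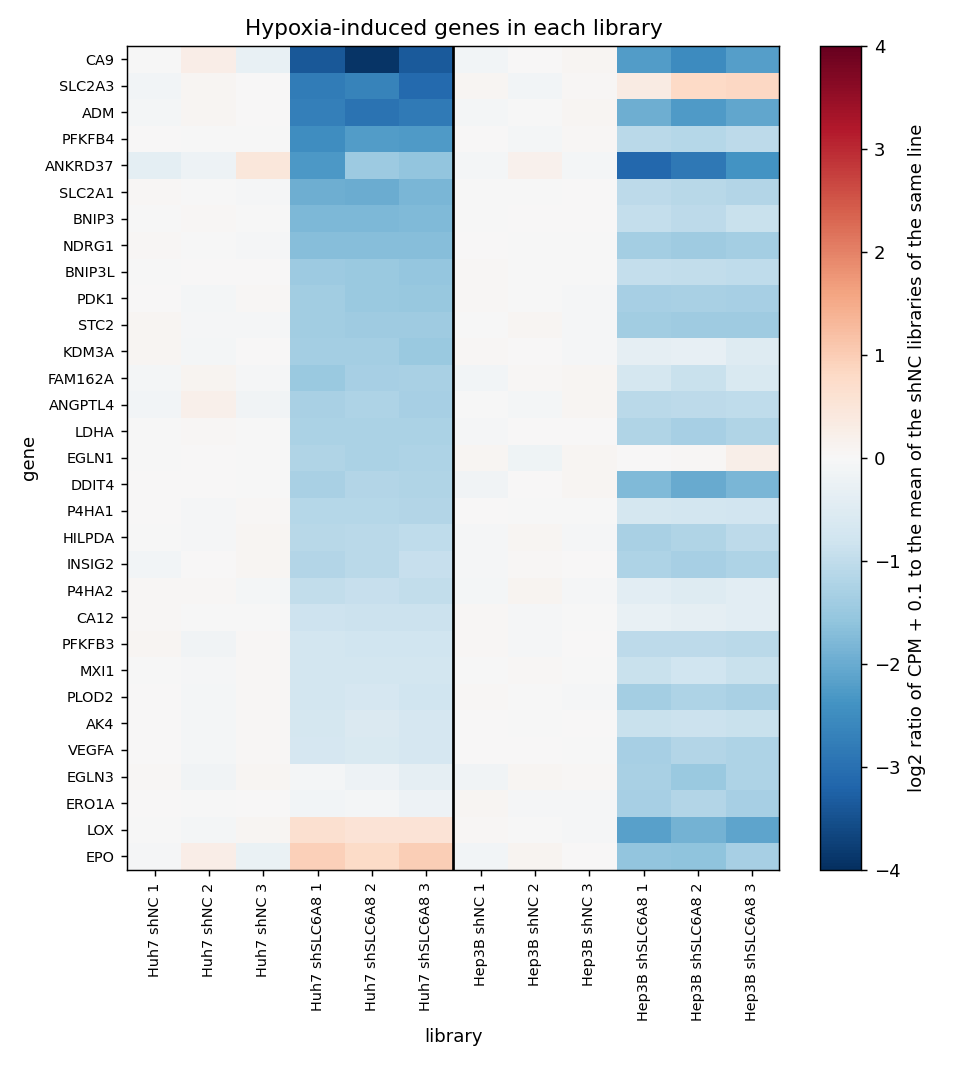
Log2 ratio of CPM + 0.1 to the mean of the shNC libraries of the same line (colour) for 31 of the 32 hypoxia-induced genes (vertical axis) in each of the 12 libraries (horizontal axis; Huh7 left of the line, Hep3B right). Knockdown libraries lie below the controls for most genes in both lines; LOX and EPO were higher in Huh7 and lower in Hep3B, and SLC2A3 was lower in Huh7 and higher in Hep3B.

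Of 31 targets of ATF4, the transcription factor of the integrated stress response, 25 fell and 4 rose in Huh7 (25 and 5 adjusted over the list alone), including the growth factor GDF15 (325 to 30 CPM) and the amino acid transporter subunit SLC3A2 (703 to 153 CPM). Of 32 antioxidant genes 28 fell and 3 rose, as they did adjusted over the list alone; the aldo-keto reductase AKR1B10 fell by 3.57 and OSGIN1 fell by 3.35. CBR3, a carbonyl reductase, had the largest decrease of the genes ranked, from 25.3 ± 0.86 to 0.437 ± 0.219 CPM, though an antisense gene overlaps it. In the autophagy and lysosome list 24 of 28 fell (24 adjusted over the list alone), led by the protease CTSL and the cargo receptor SQSTM1 (2755 to 671 CPM), with adjusted p = 0.0644 with an estimated correlation. Of 15 heat shock genes 7 fell and 4 rose, and of 22 p53 targets 10 fell and 4 rose, all as adjusted over the list alone, with adjusted p = 0.277 and p = 0.0644 with an estimated correlation. The co-chaperone BAG3 fell by 1.69 and the cell-cycle inhibitor CDKN1A fell by 2.66.

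Of 15 YAP and TEAD targets 12 fell and 1 rose in Huh7 (12 and 1 adjusted over the list alone), among them CCN1 (-3.85 ± 0.07) and ANKRD1 (-4.27 ± 0.07), with adjusted p = 0.0574 with an estimated correlation. Of 22 immediate early genes 14 fell and 3 rose (14 and 4 adjusted over the list alone); the phosphatase DUSP1 and the transcription factor JUN fell by 2.85 and 1.95. In the matrix list 18 of 29 fell and 5 rose (18 and 5 adjusted over the list alone). The TGF-beta and BMP list had 8 of 17 lower and 5 higher (9 and 6 adjusted over the list alone; adjusted p = 0.0961 with an estimated correlation), and the list of epithelial and mesenchymal state 10 of 19 lower and 4 higher (10 and 4 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation). Its members moved both ways, with the tight-junction genes CLDN4 at -2.15 ± 0.07 and CLDN1 at 0.40 ± 0.05, the intermediate filament VIM at -1.20 ± 0.06 and the integrin ITGB4 at 1.80 ± 0.22.

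Proliferation genes rose in Huh7: 32 of 34 genes of G2 and mitosis and 36 of 40 of DNA replication were higher, with 0 and 1 lower, the same counts adjusted over the list alone. CCNA2 rose by 1.15 and MCM6 by 1.12. Hepatocyte transcription factors rose in 15 of 20 cases and fell in 1 (15 and 1 adjusted over the list alone), with FOXA1 at 1.80 ± 0.07 and the bile acid receptor NR1H4 at 1.17 ± 0.05. These 3 lists and those of ATF4 targets, antioxidant, matrix and immediate early genes kept their calls with an estimated correlation, at adjusted p-values from 0.0098 to 0.0458. Secreted liver proteins rose in 27 of 35 cases and fell in 3 (27 and 3 adjusted over the list alone), such as kininogen KNG1 (1.55 ± 0.06), while AMBP and FGA fell; adjusted p = 0.176 with an estimated correlation.

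Fatty acid synthesis and storage rose in 14 of 23 cases and fell in 5 in Huh7 and fatty acid oxidation rose in 15 of 25 and fell in 5, all as adjusted over the list alone (adjusted p = 0.152 and p = 0.303 with an estimated correlation); GPAM, the first enzyme of glycerolipid synthesis, rose by 2.91. Arginine, glycine and methionine genes were higher in 12 of 23 cases and lower in 4, and Wnt targets in 9 of 16 and 3, unchanged adjusted over the list alone (adjusted p = 0.266 and p = 0.14 with an estimated correlation). Chaperones of the endoplasmic reticulum were higher in 11 of 21 cases and lower in 6, and oncofetal genes in 10 of 17 and 5, again the same adjusted over the list alone (adjusted p = 0.159 and p = 0.0961 with an estimated correlation). Cholangiocyte markers fell in 6 of 9 cases and rose in 1, also adjusted over the list alone, with SPP1, the osteopontin gene, down from 234 to 17.6 CPM (adjusted p = 0.0644 with an estimated correlation). Ribosomal protein genes fell in 32 of 54 cases and rose in 0, also adjusted over the list alone, but that call was lost with library totals (adjusted p = 0.0882), without Huh7 shNC replicate 2 (adjusted p = 0.119), without Huh7 shSLC6A8 replicate 1 (adjusted p = 0.0664) and with an estimated correlation (adjusted p = 0.717). With length and GC trends removed the list of ribosomal proteins turned, with a median of 0.01 against -0.17 (adjusted p = 0.923). Of the other 17 lists, 16 did not pass in Huh7 and 1 had under 5 measured members.

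Of the creatine list itself, 3 of 8 genes rose and 2 fell in Huh7 (4 and 2 adjusted over the list alone), and camera's adjusted p was 0.209. The list holds SLC6A8, the target of the hairpin; without it, a test chosen after the data were examined, the other 7 members had a median of 0.43 and an adjusted p of 0.0151, or 0.171 with an estimated correlation. GATM, the first enzyme of creatine synthesis (chromosome 15, 45361124 to 45402227), rose from 7.09 to 50.6 CPM (2.84 ± 0.10), and GAMT, the second, rose from 37.7 to 96.1 CPM (1.35 ± 0.08). CKM, the muscle creatine kinase, rose by 1.03 at 0.837 CPM in controls. CKB, the brain-type kinase, was at -0.20 ± 0.05, a call lost without Huh7 shSLC6A8 replicate 2 (-0.14, adjusted p = 0.0532 by edgeR), with library totals (-0.09, adjusted p = 0.12) and with length and GC trends removed (-0.06, adjusted p = 0.0986). CKMT1A, CKMT1B and SLC22A15 were at 0.43, 0.21 and -0.06 and did not pass; the near-identical CKMT1 copies share reads. CKMT1A passed without Huh7 shSLC6A8 replicate 2 (0.62, adjusted p = 0.00782 by edgeR) and in 5 other settings, with library totals (0.53, adjusted p = 0.0189) and removal of length and GC trends (0.57, adjusted p = 0.00842) among them. Other large increases were in the glucose transporter SLC2A2 (4.11 ± 0.18), the lectin MBL2 (3.23 ± 0.18), the receptor FGFR2 (3.25 ± 0.24), FAM20A (3.38 ± 0.25), PRR15L (3.43 ± 0.27) and HPR (5.09 ± 0.36), whose reads may be shared with HP. Large decreases were in ANXA1 (173 to 6.72 CPM), the collagenase MMP13 (-5.18 ± 0.22), HSPA6 (-4.96 ± 0.37), TRIM54 (-4.82 ± 0.26), BBOX1 (-4.53 ± 0.23) and LINC01564 (-5.29 ± 0.25).

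In Hep3B, hypoxia-induced genes were lower in the knockdown libraries. Glycolytic genes, secreted liver proteins and chaperones of the endoplasmic reticulum were also called lower by camera, but these calls were lost with an estimated correlation (adjusted p = 0.0775, p = 0.0913 and p = 0.132). NDRG1, a stress gene of hypoxia, fell from 644 to 247 CPM. AHSG, the fetuin-A gene, fell from 3267 to 714 CPM, and angiotensinogen, AGT, fell from 557 to 173 CPM. TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose from 14.3 to 149 CPM (3.39 ± 0.07). Of 16181 genes tested, 6488 passed, 3061 higher and 3427 lower, by edgeR at an adjusted p of 0.05, and 1107 of them changed by a log2 fold of 1 or more. The authors' deposited table marked 1036 genes; 978 were called here in the same direction and 0 in the opposite one. With library totals the median log2 change of all genes was 0.203, against 0.0129 with TMM, and 76.2% of calls were higher, against 47.2%, so directions of small changes in Hep3B hold relative to TMM scaling.

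Of 32 hypoxia-induced genes 30 fell and 1 rose in Hep3B, also adjusted over the list alone, with a median of -1.21 and a camera adjusted p of 1.27e-68. Camera called 22 of 39 lists in Hep3B, at adjusted p-values of at most 0.0397, and the hypoxia list was the 1 whose call held with an estimated correlation (adjusted p = 0.00134). The member that rose was the glucose transporter SLC2A3 (0.68 ± 0.18), a call lost without Hep3B shNC replicate 2 (0.62, adjusted p = 0.0627 by edgeR). Glycolysis genes fell in 16 of 18 cases and rose in 1, also adjusted over the list alone (adjusted p = 0.0775 with an estimated correlation); the enolase ENO2 fell by 1.93, the isomerase GPI fell by 1.33, and the lactate transporter SLC16A1 rose by 0.54. Gluconeogenesis and glycogen genes fell in 7 of 9 cases and rose in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation), with the branching enzyme GBE1 at -1.21 ± 0.06. TCA cycle genes fell in 13 of 21 cases and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.281 with an estimated correlation). SDHD, a subunit of succinate dehydrogenase, fell from 64.4 to 14.3 CPM. Nuclear-coded oxidative phosphorylation genes fell in 21 of 72 cases and rose in 1 (18 and 1 adjusted over the list alone), and mitochondrially coded ones fell in 9 of 13 and rose in 1, also adjusted over the list alone (adjusted p = 0.742 and p = 0.281 with an estimated correlation). Both calls were lost with library totals (adjusted p = 0.208 and adjusted p = 0.149), where the nuclear-coded median turned from -0.09 to 0.10. The nuclear-coded call was also lost without Hep3B shNC replicate 2 (adjusted p = 0.0762), shNC replicate 3 (adjusted p = 0.107) or shSLC6A8 replicate 2 (adjusted p = 0.37). The share of counts from mitochondrial ribosomal RNA was 2.18% ± 0.015 in Hep3B controls and 1.14% ± 0.023 in the knockdown libraries, and 1.09% ± 0.031 and 0.71% in Huh7 (mean ± SD, n = 3).

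Secreted liver proteins fell in 23 of 33 cases and rose in 4 in Hep3B, also adjusted over the list alone (adjusted p = 0.0913 with an estimated correlation). The complement gene C5 and the hemopexin gene HPX rose, by 0.83 and 1.19. Endoplasmic reticulum chaperones and their regulators fell in 16 of 21 cases and rose in 0, also adjusted over the list alone (adjusted p = 0.132 with an estimated correlation), with calnexin, CANX, down from 635 to 365 CPM. Iron-handling genes fell in 10 of 20 cases and rose in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation); ceruloplasmin, CP, fell by 1.69 and transferrin, TF, fell by 1.29, while the hepcidin gene HAMP rose by 2.23. Immediate early genes fell in 16 of 21 cases and rose in 0 (16 and 1 adjusted over the list alone; adjusted p = 0.0913 with an estimated correlation), with FOS at -2.78 ± 0.14 and EGR1 at -1.81 ± 0.10. Xenobiotic and bile acid genes fell in 7 of 16 cases and rose in 3 (7 and 4 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation), led by the cytochrome CYP2B6 (37.4 to 2.97 CPM).

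DNA replication genes rose in 21 of 40 cases and fell in 3 in Hep3B (23 and 3 adjusted over the list alone; adjusted p = 0.0913 with an estimated correlation), with E2F2 at 1.01 ± 0.12. NF-kB and inflammatory genes rose in 10 of 20 cases and fell in 3 (10 and 4 adjusted over the list alone; adjusted p = 0.0913 with an estimated correlation); the chemokines CXCL3 and CXCL10 rose by 1.55 and 1.45. Replication-dependent histone genes, whose copies share reads, rose in 5 of 13 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.401 with an estimated correlation). Smaller decreases passed for antioxidant genes (14 of 29 lower, 4 higher; 15 and 4 adjusted over the list alone), fatty acid oxidation (14 of 25 lower, 4 higher; 15 and 4 adjusted over the list alone) and autophagy and lysosome genes (18 of 28 lower, 1 higher; 19 and 1 adjusted over the list alone). With an estimated correlation their adjusted p-values were p = 0.252, p = 0.334 and p = 0.377. The calls of antioxidant and histone genes were lost with library totals (adjusted p = 0.0898 for each). The antioxidant median then went from -0.208 to -0.018, while the histone median rose from 0.507 to 0.697. Arginine and methionine genes (12 of 21 lower, 3 higher, also adjusted over the list alone), Wnt targets (8 of 16 lower, 3 higher; 8 and 4 adjusted over the list alone) and ribosomal protein genes (27 of 54 lower, 0 higher; 32 and 0 adjusted over the list alone) had adjusted p = 0.246, p = 0.281 and p = 0.718 with an estimated correlation. Matrix genes (11 of 26 lower, 8 higher; 11 and 10 adjusted over the list alone) had adjusted p = 0.164 with an estimated correlation, and their median turned from -0.10 to 0.09 with library totals.

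Of the creatine list 3 of 7 genes fell and 1 rose in Hep3B (4 and 2 adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation), and SLC6A8 itself was among the 3. Camera's call rested on SLC6A8: without it the other 6 had a median of -0.08 and an adjusted p of 0.686. SLC22A15, a carrier of zwitterions, fell from 3.76 to 0.591 CPM. CKM fell by 0.37, a call lost with library totals (-0.18, adjusted p = 0.107 by edgeR), and CKB rose by 0.34. GATM, GAMT and SLC16A12 were at -0.52, 0.23 and 0.21 and did not pass by edgeR. GATM passed with a mean log2 CPM of 1 or more (adjusted p = 0.0492) and in 1 fit of all libraries (adjusted p = 0.0283). GAMT passed with library totals (0.42, adjusted p = 0.00267), no low-count filter (adjusted p = 0.00217), the replicate block (adjusted p = 0.0479) and length and GC trends removed (0.31, adjusted p = 0.000239), and without Hep3B shSLC6A8 replicate 2 (0.32, adjusted p = 0.00499). Other large decreases were in ANGPTL8 (77.5 to 3.12 CPM), a regulator of lipoprotein lipase, PTGDS (-4.13 ± 0.15), B3GNT3 (-5.79 ± 0.32), PLAC8 (-3.40 ± 0.11) and IGFBP1 (-3.31 ± 0.18). Large increases were in TUBA1A (8.67 to 92.9 CPM), a tubulin with near-identical copies, VCAM1 (3.59 ± 0.25), SLC17A4 (3.17 ± 0.31) and CCDC103 (3.01 ± 0.26). EXOSC6 had 0 counts in all 3 controls and 0.819, 7.57 and 8.70 CPM in the knockdown libraries, at least 119-fold higher against a floor of 3 counts over the group. Its call was lost without Hep3B shNC replicate 1 (adjusted p = 0.0615 by edgeR) and without Hep3B shSLC6A8 replicate 2 (adjusted p = 0.257), and also with no low-count filter (adjusted p = 0.28) and with length and GC trends removed (adjusted p = 0.13). TRIM39-RPP21, a readthrough gene that shares reads with its neighbours, was at 3.26 ± 0.84; its call was lost without Hep3B shNC replicate 3 (2.94, adjusted p = 0.0862 by edgeR), without shSLC6A8 replicate 2 (3.15, adjusted p = 0.148) or 3 (2.79, adjusted p = 0.0908) and in 6 other settings, with DESeq2 and limma-voom among them, and without shNC replicate 1 it was at 5.39 (adjusted p = 0.0187).

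**Figure D3:**
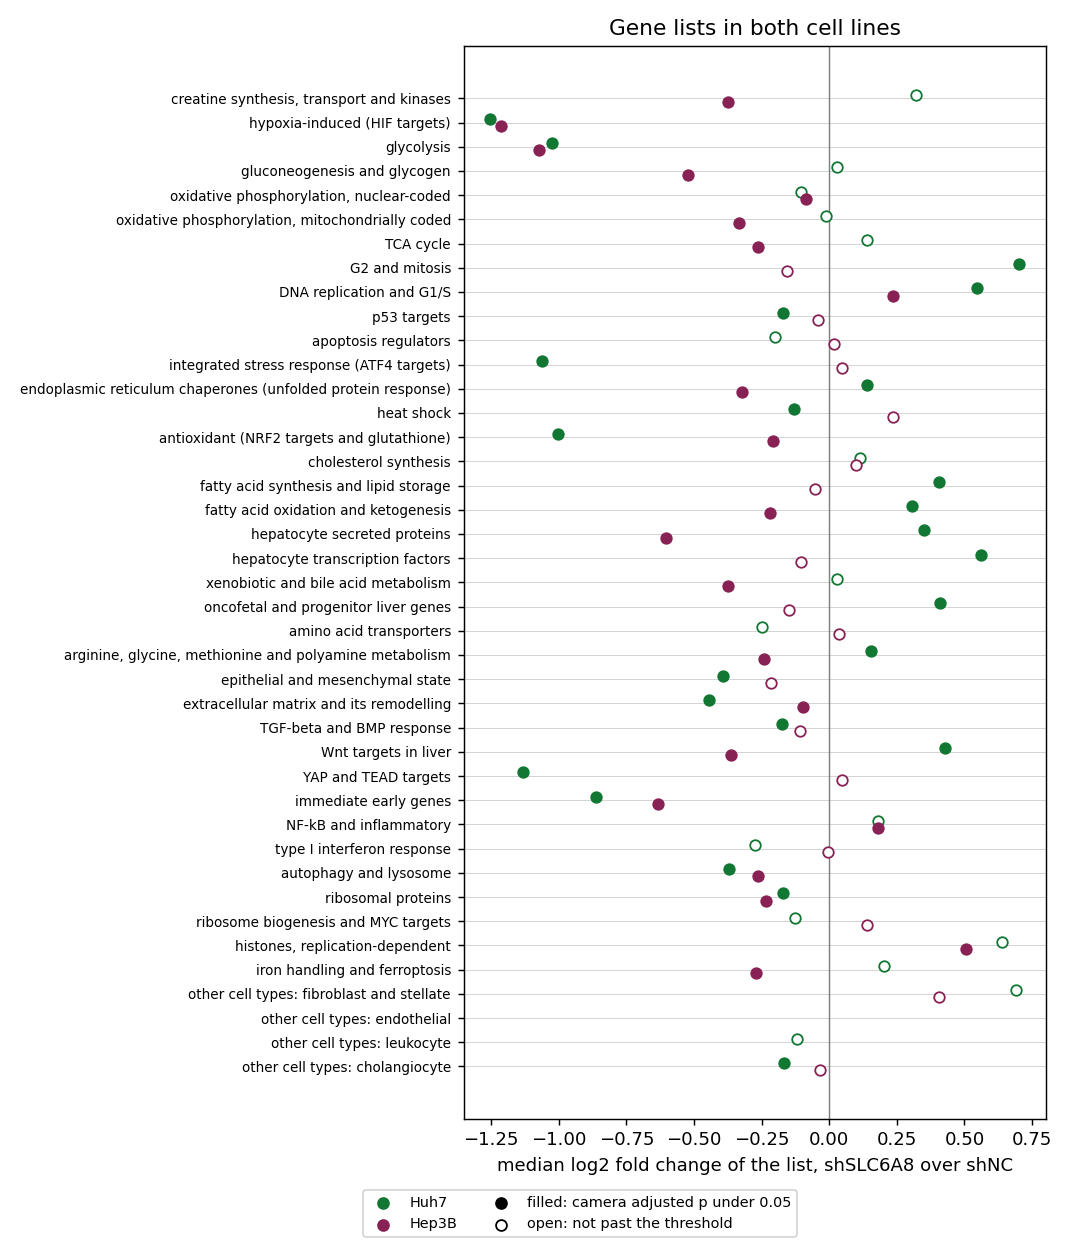
Median log2 fold change (shSLC6A8 over shNC, horizontal axis) of each gene list with 5 or more measured genes (vertical axis) in Huh7 (green) and Hep3B (purple); filled points had a camera adjusted p under 0.05. The hypoxia list lies at -1.25 and -1.21 and secreted proteins at 0.35 in Huh7 and -0.60 in Hep3B.

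Which changes the lines shared was asked next; the comparisons have no control library in common. Genes were ranked by the change in the line where each moved less, given a mean log2 CPM of 1 or more in both. CA9, FOS, the aldolase ALDOC, the glucokinase regulator GCKR and SDCBP2 were among the genes with the largest shared decreases by that rank. HSPA6 fell by 4.96 in Huh7 and 5.20 in Hep3B but was not ranked, since it lay below that level in Hep3B (2.89 to 0.0737 CPM). CA9 fell from 5.62 to 0.392 CPM in Huh7 and from 536 to 108 CPM in Hep3B, and ALDOC fell by 2.18 and 2.31 on the log2 scale. Ranked in the same way, the genes that rose most in both were AFF3, MYB, COL26A1, SCUBE3, TBX2 and CXCL10. TBX2 was at 1.44 ± 0.12 in Huh7 and 1.59 ± 0.10 in Hep3B. Over 14796 genes tested in both lines, 2164 passed in the same direction and 2089 in opposite directions. The shared counts were 1.11 times those of independent lists in each direction. There were 1026 higher in both against 926.5 and 1138 lower in both against 1024 (p = 1.14e-05 and p = 1.34e-06 by Fisher's exact test). Genes higher in Huh7 and lower in Hep3B numbered 1210 against 1057.4, and those the other way 879 against 897.2 (p = 1.48e-10 and p = 0.419 by Fisher's exact test). The test treats genes as independent. Across genes, which are not independent replicates, the fold changes had Pearson r = 0.033 and Spearman rho = 0.0137. At a log2 fold of 1 or more, 97 genes fell in both lines against 28.3 for independent lists and 58 rose in both against 26.0, but opposite changes were also more frequent than that, with 81 against 33.7 and 46 against 21.9. At that fold limit Fisher's exact test, two-sided, gave p = 1.16e-27 for the shared decreases and p = 9.38e-14 for genes higher in Huh7 and lower in Hep3B.

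**Figure D4:**
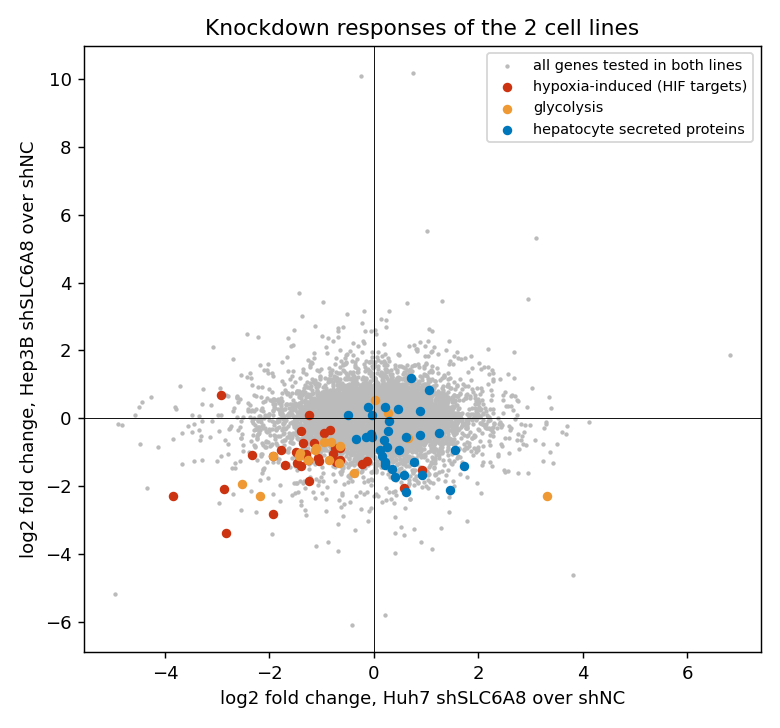
Log2 fold change (shSLC6A8 over shNC) in Huh7 (horizontal axis) against Hep3B (vertical axis) for 14796 genes tested in both, with 3 gene lists in colour. Hypoxia-induced and glycolysis genes lie mostly at the lower left, and secreted liver proteins mostly at the lower right; across all genes r = 0.033.

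The response to the hairpin differed between the lines in many genes. ANKRD1, a YAP target (chromosome 10, 90912096 to 90921087), fell by 4.27 in Huh7 and rose by 0.63 in Hep3B, a difference of 4.90. In the other direction, DKK1, a secreted Wnt inhibitor, rose from 25.2 to 117 CPM in Huh7 and fell from 843 to 485 CPM in Hep3B. ANPEP, an aminopeptidase, and UGT2B4, a glucuronosyltransferase with close paralogs, also rose in Huh7 (1.03 and 1.23) and fell in Hep3B (-1.83 and -1.78). Of 18570 genes in one fit of all 12 libraries, 8753 had an interaction past an adjusted p of 0.05 by edgeR. Of these, 4292 had the more positive response in Hep3B and 4461 in Huh7, and 3078 differed by a log2 fold of 1 or more. The separate fits tested 14796 genes in both lines, so the 18570 include genes that did not pass the filter in a line. Among those called were LDHB and HPR, which were not tested in Hep3B. For such genes the difference may rest on the response of a single line. Among the lists, a camera test of the difference, chosen after the data were examined, called 22 of 41, of which 13 held with an estimated correlation. Secreted liver proteins had a mean difference of -1.12 (adjusted p = 0.0161 with an estimated correlation), G2 and mitosis of -0.77, antioxidant genes of 0.93 and YAP targets of 1.44. For the hypoxia list the test of the difference gave an adjusted p of 0.471, which does not show that the responses were equal.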

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

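The genes and lists in this and the next paragraph were picked out because the knockdown response differed between the lines by a test of the difference itself. The tests of lists between lines, of the creatine list without SLC6A8, of scaling for hypoxia and glycolysis genes and of weaker oxygen deprivation were chosen only after the result was seen. Over all genes of the joint fit, 8753 of 18570 differed by edgeR's interaction test, and the 18570 include genes not tested in a line alone. The log2 change of SLC6A8 differed by -1.47 ± 0.10 (Hep3B minus Huh7; adjusted p = 2.55e-09). The differences were -2.86 for ANPEP, -3.01 for DKK1 and -3.01 for UGT2B4, and in the other direction 4.90 for ANKRD1. Of 269 named genes 219 passed this test, with genes not tested in Hep3B, such as LDHB, among them. Single values are given for SLC6A8 and for the genes chosen as clearest opposite changes.

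The lists whose response was more negative in Hep3B, with their mean difference of log2 changes (Hep3B minus Huh7), were secreted liver proteins (-1.121), creatine (-0.975), G2 and mitosis (-0.77), arginine and methionine metabolism (-0.747), fatty acid oxidation (-0.718), hepatocyte transcription factors (-0.696), Wnt targets (-0.678), xenobiotic metabolism (-0.63), endoplasmic reticulum chaperones (-0.621), TCA cycle (-0.524), oncofetal genes (-0.523), fatty acid synthesis (-0.462), DNA replication (-0.391) and iron handling (-0.031). More positive in Hep3B were YAP targets (1.437), antioxidant genes (0.926), ATF4 targets (0.858), matrix genes (0.647), heat shock genes (0.531), autophagy (0.378), ribosome biogenesis (0.292) and NF-kB genes (0.235). These are 22 of 41 lists by camera's preset correlation; 13 held with an estimated correlation. Those lost with it were creatine (adjusted p = 0.1), TCA cycle (adjusted p = 0.138), heat shock (adjusted p = 0.133), fatty acid oxidation (adjusted p = 0.104), autophagy (adjusted p = 0.167), ribosome biogenesis (adjusted p = 0.234) and xenobiotic, matrix and iron handling genes (adjusted p = 0.0845 for each). The call of iron handling was also lost with library totals (adjusted p = 0.113). The creatine list holds SLC6A8, the target of the hairpin, and without it the call was lost (mean difference -0.914, adjusted p = 0.053).

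Hypoxia-induced and glycolysis genes were lower in both lines, though the call of glycolysis in Hep3B was lost with an estimated correlation (adjusted p = 0.0775). By camera the difference between the lines did not pass for these lists (adjusted p = 0.471 and adjusted p = 0.815), which does not show that the responses were equal. The choice of TMM over library totals did not account for the decreases. With library totals the median of their members, in the line where it was higher, was -0.92 (95% bootstrap interval over members -1.089 to -0.765). Such intervals, here and below, resample the genes of a list and do not measure the spread between libraries. Gene length and GC content are argued against by -1.085 (-1.272 to -0.9) after their trend was removed. Weaker or shorter oxygen deprivation of the knockdown cultures cannot be told apart from an effect of the knockdown: 90.6% of hypoxia members were lower in the line with fewer, as both would give, and no normoxic library was analysed here. Whether the hairpin acts on other targets stays open and was not tested.

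Secreted liver proteins were higher in Huh7 and lower in Hep3B by camera's preset correlation. With an estimated correlation both calls were lost (adjusted p = 0.176 and p = 0.0913), while that of the difference between the lines held (adjusted p = 0.0161). With library totals the difference of the medians was -0.87 (-1.456 to -0.646), so the choice of TMM over library totals did not account for it. That choice moves all genes of a line about alike. The median of all genes went from 0.001 to 0.105 in Huh7 and from 0.0129 to 0.203 in Hep3B. The value therefore tests only the choice between these scalings. With length and GC trends removed the difference was -1.07 (-1.565 to -0.868), so these trends do not account for it. Without the 5 members with the most reads it was -1.018 (-1.653 to -0.714). Medians of 35 and 33 members hardly depend on 5 of them, so this removal could not decide the role of abundant genes. The pattern was spread over many members, with 27 of 35 higher and 3 lower in Huh7 and 23 of 33 lower and 4 higher in Hep3B. A difference between the lines in how they respond may be the source, as a hypothesis found on the same data; the knockdown was also deeper in Hep3B, which was not tested as a cause.

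Fold changes were nearly uncorrelated between the lines across genes. Noise between libraries is argued against, since fold changes from separate replicates of a line correlated at 0.636 or more (0.636 to 0.802 over pairings). Differences between the cultures behind the groups could not be tested, since the labels do not say whether replicates were separate cultures. With length and GC trends removed the correlation between lines was 0.0297. Cell line remains a candidate source, as a hypothesis, with knockdown depth and differences between cultures left open.

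Other splits of the 6 libraries of a line are too few (10) for a share under 0.05. The real split gave 10525 genes in Huh7 and 6488 in Hep3B against a highest other of 0 in each. For lists the real split gave 24 in Huh7 against a highest other of 17 and 22 in Hep3B against 13. Camera with the preset correlation called from 9 to 17 lists in Huh7 and 2 to 13 in Hep3B in splits where edgeR called 0 genes. Those splits mix libraries of both groups and keep part of the real difference, so these are not counts of false calls. In simulated counts with 1 raised list and no correlation between genes, camera called 1 of 39 other lists in Huh7 and 0 of 38 in Hep3B. For results over both lines, 100 splits do not decide whether chance can be excluded, although few gave as large a count. The shared response was 2164 genes (highest other 2089, 1 split as large) and the difference 8753 genes (highest other 8883, 2 splits as large). The real split itself is counted in each of these numbers of splits, so no other split reached the shared count. Both of these highest values came from the draw that kept the real grouping in both lines and swapped the group names in 1 of them. Such counts follow from each line having a response, and they were nearly the same with the direction of 1 line reversed. With neither line in its real grouping the highest were 0 and 2.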

How the results depend on the processing

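The removal of length and GC trends, library totals for lists, the creatine list without SLC6A8, the list test of the difference and alternatives for the correlation were chosen only after the result was seen. Of the values of named genes under the other settings, 5194 kept their side of the threshold, 42 no longer passed, 13 newly passed and 0 turned. For single lists these were 972, 64, 75 and 1. Turned means that the direction changed with a call on either side. A value called in neither setting could change sign and still count as kept. Fry in either direction gives no direction and was judged by the threshold alone. Named genes were largely picked by adjusted p or size of change, which favours kept calls. Counts and the correlation stayed within limits in 249 cases and moved in 24. At a log2 fold of 1 or more, the genes called in Huh7 were 2584 (1277 higher, 1307 lower) and the genes called in Hep3B 1107 (507 and 600). The genes shared by the lines were then 155 (58 higher, 97 lower), with 127 opposite, since that threshold passes fewer genes. At an adjusted p under 0.01 Hep3B had 4206 genes, 1774 higher. Library totals gave 6230 higher and 1941 lower in Hep3B; the cause was not tested. With estimated correlations 9 and 1 lists passed; fry in one direction gave 37 in Huh7, and in either direction 40 and 38, since it makes no comparison with other genes. The Huh7 list of ribosomal proteins turned with length and GC trends removed (adjusted p = 0.9231). Log2 changes rose with gene length in Huh7 (Spearman rho 0.173), against 0.012 in Hep3B. Which of the trends made the list turn was not tested. The correlation between the lines was -0.0139 without a filter and 0.0041 to 0.0597 leaving out 1 library.

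Leaving out 1 library, the genes called in Huh7 ran from 9722 to 10508, the genes called in Hep3B from 4905 to 6513, the genes shared by the lines from 1633 to 2189 and the genes that differed between the lines from 8150 to 8948, with 23 to 24 and 21 to 22 lists. Without Huh7 shNC replicate 2 the list of amino acid transporters passed (adjusted p = 0.0233), and without Hep3B shSLC6A8 replicate 2 that of ribosome biogenesis and MYC targets (adjusted p = 0.0452). DESeq2 called 9188 and 5631 of the edgeR genes in the same direction. With length and GC trends removed, 8 Huh7 calls turned. No value could be had for 31 pairs of gene and setting, and pseudocounts were not run because counts were deposited.

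With the replicate block, the genes called in Huh7 were 10125, the genes called in Hep3B 6221, the genes shared by the lines 2017 and the genes that differed between the lines 8382, with 24 and 22 lists. Deviations of libraries with the same number correlated at 0.011, -0.13 and -0.101 in Huh7 and -0.109, -0.154 and 0.275 in Hep3B. This gave little sign of pairing by number, though 3 libraries per group cannot exclude it. Not every sample correlated best with its own number. Hep3B shNC replicate 1 was at 0.438 with shSLC6A8 replicate 2 and at -0.37 with shSLC6A8 replicate 3, and the source of this was not tested. The block ended the call of TRIM39-RPP21 in Hep3B (adjusted p = 0.187) and brought GAMT in Hep3B past the threshold (adjusted p = 0.0479); it changed no other call of a named gene or list.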

Other observations

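Library totals and removal of length and GC trends for lists were chosen only after the result was seen; the other tests here were fixed before. In Huh7 the lists that camera did not call had adjusted p-values from 0.09 to 0.821. Cholesterol synthesis genes were higher in 12 of 24 cases and lower in 6, apoptosis regulators lower in 11 of 22 and higher in 1, nuclear-coded oxidative phosphorylation lower in 30 of 72 and higher in 15, and TCA cycle higher in 10 of 21 and lower in 3. Amino acid transporters were lower in 14 of 27 cases and higher in 8, ribosome biogenesis lower in 13 of 25 and higher in 5, interferon genes lower in 9 of 23 and higher in 7, and histones higher in 10 of 18 and lower in 3. Gluconeogenesis (5 higher, 4 lower of 12) and xenobiotic genes (8 and 6 of 20) went both ways, as did fibroblast markers (4 and 1 of 7) and leukocyte markers (2 and 3 of 7). Median, mean and test differed in sign for mitochondrially coded oxidative phosphorylation (-0.01, 0.07, higher; 3 higher and 4 lower of 13), NF-kB genes (0.18, 0.03, lower; 11 and 9 of 23) and iron handling (0.20, -0.17, lower; 11 and 8 of 19). Adjusted over the list alone these counts were the same, except 4 lower for the TCA cycle. With length and GC trends removed the medians of nuclear-coded (-0.11 to 0.10) and mitochondrially coded oxidative phosphorylation (to 0.17) turned to above 0 and that of gluconeogenesis from 0.03 to -0.06. With library totals the mitochondrially coded median turned to 0.09, and the nuclear-coded one was -0.001. Endothelial markers, with 4 measured, were not tested (1 higher, 2 lower).

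In Hep3B the lists that were not called had adjusted p-values from 0.0874 to 0.745. Genes of G2 and mitosis were lower in 14 of 34 cases and higher in 1 (15 and 1 adjusted over the list alone), heat shock genes higher in 9 of 14 and lower in 2 (the same adjusted over the list alone), ribosome biogenesis higher in 11 of 25 and lower in 3 (12 and 3 adjusted over the list alone), and cholesterol synthesis higher in 8 of 24 and lower in 4 (9 and 4 adjusted over the list alone). Hepatocyte transcription factors (3 higher, 7 lower of 19), oncofetal genes (5 and 8 of 19), the epithelial and mesenchymal list (4 and 10 of 19), p53 targets (6 and 7 of 21), apoptosis regulators (5 and 4 of 22) and fatty acid synthesis (7 and 6 of 22) went both ways. Adjusted over the list alone these were 3 and 7, 6 and 8, 5 and 10, 7 and 8, 5 and 5, and 7 and 7. So did YAP targets (4 and 2 of 14), cholangiocyte markers (1 and 3 of 9) and fibroblast markers (3 and 1 of 7; 3 and 2 adjusted over the list alone, which changed neither of the other 2). Median and mean or test differed in sign for ATF4 targets (0.05, -0.10, lower; 8 higher and 10 lower of 30), amino acid transporters (0.04, -0.15, lower; 6 and 8 of 24), TGF-beta genes (-0.11, 0.07, lower; 8 and 7 of 17) and interferon genes (-0.004, 0.05, higher; 6 and 3 of 21). Adjusted over the list alone these were 9 and 11, 7 and 9, 8 and 8, and 6 and 3. With library totals the medians of G2 and mitosis, p53 targets, fatty acid synthesis, hepatocyte transcription factors, oncofetal, TGF-beta, interferon and cholangiocyte lists turned from below 0 to above 0, as did those of p53 targets and interferon genes with length and GC trends removed. Leukocyte markers (0 higher and 2 lower of 4) and endothelial markers (0 and 1 of 2) were not tested, with the same counts adjusted over the list alone.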
